A study of Arabidopsis thaliana with 2 samples.

How the data were processed

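Genomic DNA of Arabidopsis thaliana seedlings was sequenced on a HiSeq2000 instrument, per the labels' protocols, from 2 pools of the progeny of the fifth cross of the dominant mutant potent to the ecotype Landsberg erecta (Ler). One pool held seedlings with the potent phenotype and the other seedlings without it, with 1 sample per group, so no spread between replicates could be estimated and no test between the phenotypes was possible. The mutant arose in a Col-0 line carrying DR5, WOX5 and SCR reporters that was mutagenized with 50 mM ethyl methanesulfonate (EMS) for 12 hours. It was crossed 6 times to the parental line before 5 crosses to Ler, per the labels' protocols.

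The authors deposited a table of SNP positions, and this was the only table analysed here. Its title describes homozygous SNPs of chromosomes 1 to 5 and carries the abbreviation MT. The design text calls the seedlings with the phenotype mutant, but the sources used here do not define MT, and no column of the table names a pool. The positions are therefore called listed SNPs. Each row gives a chromosome number and a position, per the file headers, with no allele, read depth, quality, gene or predicted effect. The genome build was TAIR10, per the submitters' processing notes, and SNPs were identified with the SNPtrack pipeline, per the series' design text. The aligner, the caller's thresholds and the criterion for a homozygous site are not given in the sources used here. The read depth behind each site is unknown, so a stretch without listed SNPs can hold reference sequence, heterozygous sites or sites that were not callable. Within each chromosome the positions increased and none was repeated. In the position columns, 5 cells that were not empty could not be read as a number and were left out, as were empty cells.

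From these positions, SNPs per Mb were computed for each chromosome up to its last listed position, with exact Poisson 95% intervals. These intervals cover counting error only, and neighbouring SNPs are inherited together. SNPs were counted in consecutive 500 kb windows, the last window of each chromosome ending at its last listed position. A window was called low when it held under 20% of the median window of its chromosome. The low-density region was the longest run of low windows outside 2 Mb either side of rounded centromere positions (15, 4, 14, 4 and 12 Mb for chromosomes 1 to 5). Its length was set against the longest run in 100000 random orders of the windows within each chromosome, in a one-sided permutation test. Windows are not independent, so this p-value describes this list alone. The random orders break up neighbouring windows that are inherited together, so a small p-value is likely for any such list. Distances between neighbouring SNPs were ranked per chromosome. On 20 simulated lists with a 4 Mb segment thinned to 5% of its density, the window method recovered the segment in 20, and it made 0 calls in 20 lists without one. The simulated clumps were spread evenly along each chromosome. The 0 calls therefore do not measure false calls in a list whose density varies over many Mb, as it does here.

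Genes were taken from the RefSeq annotation of TAIR10.1, whose nuclear chromosome sequences are those of TAIR10. The match was checked by shifting the annotation. The share of listed SNPs inside protein-coding genes was 44.4% unshifted, the lowest of the 11 placements tried, and 51.1% and 50.4% after shifts of 3000 bp in either direction. No coordinates of gene models are printed. All 92 genes of 6 lists (Aux/IAA repressors, auxin response factors, auxin receptors, auxin transport, lateral root and root meristem, Ler marker loci) were found by locus identifier. For each list, the median number of SNPs per gene was placed among 10000 random lists of protein-coding genes matched on 10 classes of gene length. The share of members with a listed SNP was compared with the other protein-coding genes by a two-sided Fisher exact test, Benjamini-Hochberg adjusted over the 6 lists. This test is not matched on length, and linked genes are not independent. On simulated data over 27432 genes, with the real counts put in random order, the median of a list of 25 genes left the central 95% of random lists in 20 of 20 lists given 2 more SNPs per gene but in 0 of 20 lists stripped of their SNPs, because most genes hold none. The median can therefore show an excess and not a shortage. The list mean left that range in 20 of 20 of each kind, and 20 of 20 unchanged lists stayed inside it by either. These simulated lists had 25 genes and were not matched on length. The result for the mean therefore does not carry over to shorter lists, such as the 6 auxin receptors.

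The lists, windows, tests and naming rule were fixed before the data were examined. The rule named list members with protein-changing SNPs, the Ler marker loci, genes with stop or splice-site SNPs, the 10 genes with the most SNPs, and list members inside the low-density region with the genes at its edges. Because the table gives no effects, list members are named by their number of listed SNPs instead, not all of them reported here, and the Fisher test counts any listed SNP. Planned summaries of base changes, effects, allele support and a site-by-site comparison of the pools could not be made. Alternatives varied the window size, the threshold, the median, the window start, the centromere mask, thinning to at most 1 SNP per 1 kb, and the matching of random lists. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.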

Results

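The study mapped potent, a dominant mutation found in an EMS screen for impaired lateral root formation, by crossing the Col-0 mutant repeatedly to Ler and sequencing pooled seedlings with and without the phenotype. The data analysed here are 1 list of 40612 SNP positions on the 5 chromosomes of the TAIR10 build, described by its title as homozygous. There was 1 pool per phenotype and 1 list that names neither pool. No value could therefore be set beside one from the other pool, and the read depth behind the positions is unknown. The question open to these data is how the listed SNPs are spread over the chromosomes, where they are scarce, and which genes of auxin signalling and root development they fall in.

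Chromosome 1, the longest, carried the fewest listed SNPs and the lowest density. It held 5021 SNPs, or 165 per Mb (95% Poisson interval 161 to 170). Chromosome 2 held 6812, or 346 per Mb (338 to 354), chromosome 4 held 7263, or 391 per Mb (382 to 401), chromosome 3 held 9938, or 424 per Mb (415 to 432), and chromosome 5 held 11578, or 430 per Mb (422 to 438). The interval of chromosome 1 did not overlap that of any other chromosome, while those of chromosomes 3 and 5 overlapped each other. Thinning to at most 1 SNP per 1 kb or leaving out the centromeres kept chromosome 1 lowest but changed the order of the other 4. SNPs were clumped: on chromosome 5 the median distance between neighbours was 560 bp, and on chromosome 2 it was 1138 bp.

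SNP density differed widely between parts of chromosomes 1, 3, 4 and 5, in some places over several Mb and not as a step. On chromosome 1, the first 21 Mb held 564 SNPs, or 26.9 per Mb (24.7 to 29.2), and the rest of the chromosome held 4457, or 473 per Mb (459 to 487). The densest 1 Mb window of this chromosome, from 24 to 25 Mb, held 1303 SNPs. Chromosome 4 carried 684 SNPs per Mb (668 to 700) up to 10 Mb and 49.8 per Mb (45.2 to 54.8) beyond it. Chromosome 5 carried 624 per Mb (612 to 635) up to 18 Mb and 39.2 per Mb (35.2 to 43.5) beyond it. Chromosome 3 fell from 711 per Mb (694 to 727) in its first 10 Mb to 87.7 per Mb (80.9 to 94.9) between 10 and 17 Mb, a stretch that includes the centromere, and then carried 344 per Mb (329 to 358). SNPs were not scarce at every centromere. Within 2 Mb of it, chromosomes 2, 4 and 5 held 473.5, 794 and 817 per Mb, against 313, 281 and 362 elsewhere. Chromosomes 1 and 3 held 19 and 53.25 per Mb there, against 187 and 499.8 elsewhere. On chromosome 2 the full 1 Mb windows held between 161 and 530 SNPs, and density was lowest at the end of the chromosome, where the last 0.698 Mb held 32 SNPs, or 45.9 per Mb. These boundaries were chosen after the values were seen.

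**Figure D1:**
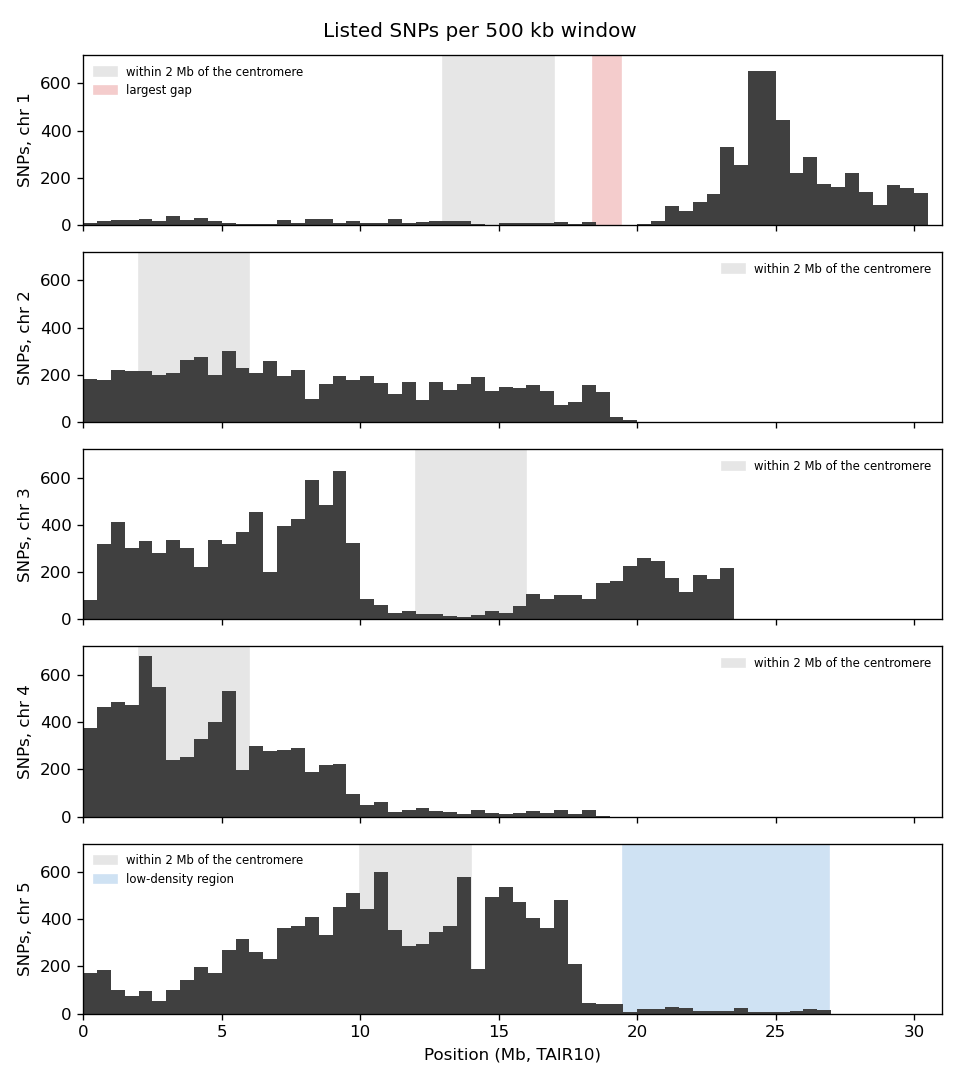
Number of listed SNPs (vertical axis) in each 500 kb window along the 5 chromosomes (horizontal axis, Mb of TAIR10), with bars starting at 0 and the last window of each chromosome ending at its last listed SNP. Grey marks 2 Mb either side of the rounded centromere, blue the low-density region of chromosome 5 and red the largest gap on chromosome 1, where the first 21 Mb hold 26.9 SNPs per Mb.

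By the rule set in advance, the low-density region lay on chromosome 5 between positions 19500001 and 26927726. It was a run of 15 low windows holding 225 SNPs, or 30.3 per Mb, across 2082 protein-coding genes. No random order of the windows gave a run as long (one-sided permutation test, p = 1e-05, the smallest the 100000 orders can give). Because the orders break up linked windows, this p-value does not single out this region. List members inside it were the Aux/IAA repressors IAA9 and IAA33, the auxin response factors ARF2 and ARF4, the auxin receptor AFB5, the auxin efflux carrier PIN2, and PLT5 and PLT7, AP2-domain transcription factors of the PLETHORA group. Each of these 8 genes had 0 listed SNPs. The region was chosen for its few SNPs, so this is no result about these genes. In the sparse segments of chromosomes 1, 4 and 5 defined below, 218 of 5420 protein-coding genes (4.02%) held a listed SNP. These segments follow another rule: the one on chromosome 5 starts at 21500001 and leaves out AFB5. The share among the 2082 genes of the region itself is not given here. The last SNP before the region, at position 19455353, lay between annotated genes, and the region ran to the last listed SNP of the chromosome. The next longest run was on chromosome 4, with 13 windows from 12500001 to 18554074 and 38.2 SNPs per Mb. The rule sets each window against its own chromosome, whose median window was 19 SNPs on chromosome 1 and 186 on chromosome 5. The place of the longest run depended on these settings. It was on chromosome 4 with 1000 kb windows (7.55 Mb), with a threshold of 50% (8.55 Mb) or with the median of all windows of the genome, 139 SNPs (6.05 Mb). It stayed on chromosome 5 but shrank from 7.43 Mb to 2.2 Mb with 100 kb windows, 2.93 Mb with 250 kb windows and 2 Mb with a threshold of 10%. With the genome median and no centromere mask, an alternative chosen after seeing the data, it was on chromosome 1, from 9000001 to 21000000, with 20.5 SNPs per Mb and 2134 protein-coding genes.

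The longest distance between neighbouring listed SNPs in the genome was on chromosome 1. No SNP was listed between positions 18390817 and 19398860, a gap of 1008 kb with 241 protein-coding genes. Both flanking SNPs lay between annotated genes. The next longest gap on this chromosome, 424 kb, lay within 2 Mb of the centromere and held 4 protein-coding genes. Elsewhere the longest gap was 332 kb on chromosome 3, 282 kb on chromosome 5, 221 kb on chromosome 4 and 177 kb on chromosome 2. On chromosome 1 the 4 windows from 18500001 to 20500000 held 6 SNPs together, or 3 per Mb, the lowest density of any run of low windows under the rule. That rank was largely set by the rule. A low window must hold far fewer SNPs on chromosome 1, whose median window was 19, than on the other chromosomes. List members inside the gap were IAA18 (AT1G51950), an Aux/IAA repressor of auxin response, and PLT2 (AT1G51190), a PLETHORA transcription factor of the root meristem. IAA18 lay 91.3 kb from the SNP that closes the gap and 914 kb from the SNP that opens it. IAA6 (AT1G52830) lay 274 kb beyond the gap and had 0 listed SNPs. Leaving out the 704 SNPs of the genome with no other listed SNP within 10 kb, an alternative chosen after seeing the data, widened the gap to 2489 kb, from 18325370 to 20814063, which takes in IAA6. Leaving out SNPs can only widen a gap, and this filter bears most on sparse stretches. The wider gap is therefore no separate support for the gap or for IAA6. These 3 genes were named after their positions were seen.

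**Figure D2:**
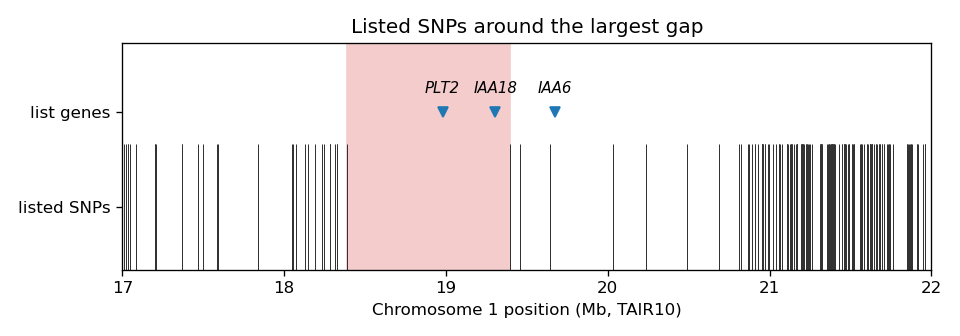
Listed SNPs (vertical lines) along chromosome 1 from 17 to 22 Mb (horizontal axis, Mb of TAIR10), with triangles at the list genes PLT2, IAA18 and IAA6. Red marks the gap of 1008 kb without a listed SNP, which holds PLT2 and IAA18.

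Of 27432 protein-coding genes, 8004 (29.2%) held at least 1 listed SNP. No allele is given, so natural differences between Col-0 and Ler cannot be told apart from changes made by EMS. A listed SNP in a gene is therefore no evidence that the gene was mutated in the screen or bears on the phenotype. Among 29 Aux/IAA repressors, 7 did (24.1%; Fisher exact test, p = 0.684, adjusted over the 6 lists p = 0.684). IAA2 had 6 SNPs and IAA19 had 5, both on chromosome 3, whereas IAA1, IAA7, IAA16, IAA26 and IAA31 had 1 each. Auxin response factors, the transcription factors that these repressors bind, had listed SNPs in 2 of 23 genes: ARF7, a regulator of lateral root initiation, had 12, and ARF11 had 1. Their share was below that of other genes before correction but not after it (Fisher exact test, p = 0.0362, adjusted p = 0.109). Of the 23, 12 lay in the sparse segments of chromosomes 1, 4 and 5, which hold 5420 (19.8%) of all protein-coding genes. These are the 3 runs of 5 Mb or more under the genome median with no centromere mask, the setting chosen after seeing the data. Shorter sparse runs were not counted as sparse segments. Outside the 3 segments, 2 of 11 auxin response factors held a SNP (Fisher exact test, p = 0.348, adjusted p = 0.418). None of the 6 auxin receptors held a listed SNP (Fisher exact test, p = 0.19, adjusted p = 0.228). This was the lowest possible count, so with 6 genes the test could not have shown a shortage.

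Auxin transport genes held listed SNPs more often than other genes. At least 1 SNP was listed in 9 of 14 (64.3%; Fisher exact test, p = 0.00677, adjusted p = 0.0406). ABCB1 had 7 SNPs, the influx carriers AUX1 and LAX1 had 4 each, LAX3 had 2 and LAX2 had 1. Among the efflux carriers, PIN5 had 3 and PIN3 had 1. This test is not matched on gene length. Their median of 1 SNP per gene stood at the 93.3 percentile of random lists matched on length, and outside the sparse segments, a restriction added after seeing the data, 9 of 13 (69.2%) held a SNP against 35.4% of all genes there (Fisher exact test, p = 0.017, adjusted p = 0.0975).

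Lateral root and root meristem genes held SNPs in 8 of 16 (50%; Fisher exact test, p = 0.0945, adjusted p = 0.142), and outside the sparse segments in 8 of 12 (66.7%; p = 0.0325, adjusted p = 0.0975), close to the share of auxin transport genes there. LBD16, SCR, WOX5, PLT1, ALF4, ACR4 and LRP1 had 2 each and PLT3 had 1. SCR and WOX5 are the genes whose promoters drive reporters of the mutagenized line. Of the 4 Ler marker loci, ER, the receptor kinase gene for which the ecotype is named, HUA2 and FRI had 1 SNP each and FLC had 0 (Fisher exact test, p = 0.0776, adjusted p = 0.142). Medians of the 6 lists stood between the 33.2 and 93.3 percentiles of length-matched random lists, but the median of most random lists was 0, so a shortage could not have shown in a median. By their means, an alternative added after seeing the data, the lists stood between the 3.96 percentile, for the auxin receptors, and the 88.6, for auxin transport. The mean of the auxin receptors was 0, so 3.96 was the lowest percentile this list could reach. A shortage among the 6 receptors therefore could not have left the central 95% by the mean either.

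Genes with the most listed SNPs lay on chromosomes 1, 2 and 3. AT3G10180 had 35, EMB2729 (AT3G20440) had 29, TOC64-III (AT3G17970), named for the translocon of the outer chloroplast membrane, had 24, and GAD2 (AT1G65960), a glutamate decarboxylase, and PIP5K9 (AT3G09920), a phosphatidylinositol phosphate kinase, had 23 each. HEB1 and TIL2 had 20 each, MAK10 and the vacuolar glucose transporter gene VGT1 had 19 each, and LETM2 had 18. Per kb of gene, TOC64-III had 5.75 SNPs and TIL2, the longest of the 10, had 1.52.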

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

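No paired analysis was possible because each phenotype has 1 pool and the table names neither. The largest gap without isolated SNPs, the combination of genome median and no mask, neighbouring genes as background, list means, counts of members with a SNP and the restriction to genes outside the sparse segments were chosen after seeing the data. Thinning to at most 1 SNP per 1 kb gave 88.1, 202, 208, 185 and 196 SNPs per Mb on chromosomes 1 to 5, and leaving out the centromeres gave 187, 313, 499.8, 281 and 362; chromosome 1 was lowest in both, and the order of the others changed in both. The low-density region kept a permutation p between 1e-05 and 0.0434, but its place did not hold. It stayed on chromosome 5 but shrank to 2.2 Mb with 100 kb windows, 2.93 Mb with 250 kb windows and 2 Mb at the 10% threshold. It moved to chromosome 4 with 1000 kb windows (7.55 Mb), at the 50% threshold (8.55 Mb) and with the genome median (6.05 Mb), and to chromosome 1 with the genome median and no centromere mask (12 Mb). Shifted windows, no mask, a 3 Mb mask and thinning left it on chromosome 5 within 1.5 times its length. The gap was the same after thinning and grew to 2489 kb when 704 SNPs without a neighbour within 10 kb were left out, a step that can only widen a gap. The auxin transport median reached the 98.4 percentile in unmatched lists and 97.9 among neighbouring genes. The number of auxin transport members with a SNP reached the 99.5 percentile among neighbouring genes. Neither background was matched on gene length, and with matching the median stood at the 93.3 percentile. The adjusted Fisher p of auxin transport rose to 0.0975 outside the sparse segments, with 9 of 13 members still holding a SNP (the cause was not tested). No other list changed its call, though medians could not show a shortage. Filters on quality or depth, and alternatives for base changes and effects, were not run because the table gives no such values.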

Other observations

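All tests reported here were chosen only after the listed positions had been examined. Listed SNPs were sparser inside protein-coding genes than outside every annotated gene. Protein-coding genes held 280 SNPs per Mb (95% Poisson interval 276 to 284), pseudogenes 370 (359 to 382), lncRNA genes 291 (266 to 317) and sequence outside every annotated gene 424 (418 to 431); the intervals of protein-coding and lncRNA genes overlapped. Outside the sparse segments the values were 345, 441, 363 and 522 per Mb, in the same order. Within the 3 sparse segments of 5 Mb or more, 218 of 5420 protein-coding genes (4.02%) held a listed SNP, against 35.4% elsewhere.

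The gap of 1008 kb on chromosome 1 was longer than the longest gaps of chromosome 3 (332 kb), chromosome 5 (282 kb) and chromosome 4 (221 kb), although the sparse segment around it, at 20.5 SNPs per Mb, was close in density to that of chromosome 5, at 27.8. The 164 SNP clusters between 9000001 and 21000000, a segment chosen after seeing the data, were placed at random with an even density. The median longest gap was then 389 kb, and a gap as long as the real one was rare (one-sided permutation test, p = 4e-05, 100000 placements). The gap had been picked as the longest of the genome, and the p-value is not corrected for that choice. The result argues only against clumped SNPs at an even density in this segment, whose 500 kb windows held between 0 and 25 SNPs. Centromere proximity does not cover the sparse part of the chromosome, because its first arm outside 2 Mb of the centromere held 33.2 SNPs per Mb (30.2 to 36.5) and its second arm 336 (327 to 346). A hypothesis from the design is that seedlings chosen for a dominant Col-0 mutation stayed heterozygous around it, which would remove sites homozygous for Ler; this holds only if the list comes from the pool with the phenotype, which the sources used here do not state, and without a list from each pool it cannot be told apart from filtering or callability. IAA18 and PLT2 were 2 list genes among 241 genes in the gap, where 0.808 would be there by chance (one-sided Fisher exact test, p = 0.194). List genes were therefore not shown to be more frequent in the gap than by chance. The test asks about the lists as a whole and cannot speak for or against either gene.

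Sparse segments of 5 Mb or more lay on 3 chromosomes with the genome median and no centromere mask, a setting chosen after seeing the data; under the rule set in advance such runs lay on chromosomes 4 and 5 alone, and the longest on chromosome 1 was 2 Mb. Under either there is more than 1 such chromosome, so heterozygosity around 1 selected mutation cannot account for all of them. Unselected segments that stayed heterozygous by chance, and sequence shared by both ecotypes, were not tested and remain open.

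The low share of auxin response factors with a listed SNP, 2 of 23, may come in part from where these genes lie. Random genes drawn from the 20 nearest on each side of each member gave a median of 3 genes with a SNP, and 2 stood at the 22.4 percentile. These draws were not matched on gene length, and members that lie close together could be drawn for each other. By the mean number of SNPs the list stood at the 91.7 percentile of these draws, with 12 of its 13 SNPs in ARF7. Outside the sparse segments 2 of 11 (18.2%) held a SNP against 35.4% of all genes there (two-sided Fisher exact test, p = 0.348). Shorter sparse runs were not removed, such as 4500001 to 8500000 on chromosome 1, at 23 SNPs per Mb, which holds ARF5 and ARF19. This comparison therefore does not take location out. A lower share apart from location is neither shown nor excluded at this number of genes.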
